A study of Arabidopsis thaliana with 2 samples.

How the data were processed

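Small RNA was measured by sequencing in 2 libraries of 1 group, wild-type Columbia seedlings 10 days old. Per the labels' protocols, total RNA was extracted with Trizol and made into libraries with Illumina's TruSeq small RNA kit. Per the submitters' processing notes, cutadapt and the genome build TAIR10 were used, with no version or role given, and other settings are not given in the sources used here. The authors deposited, for each library, raw counts of reads per distinct sequence, without genome positions, normalization or gene names. The files held sequences of 18 to 30 nt, each once. The numbers 1 and 2 of the replicates came from the labels, which do not say whether the seedlings were grown separately, so the spread between the libraries may be technical.

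Each distinct sequence was matched without mismatches to both strands of the TAIR10.1 RefSeq assembly, which served for all coordinates since the files carry none, and to its annotation. The matching was written in Python 3.11.15 with numpy 2.4.6, numba 0.67.0, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. In a test on simulated data, 19983 of 19983 sequences drawn from the genome were found at their position and 0 of 20000 random sequences of 30 nt had a match. Matches were found for 86.7% of the reads of replicate 1 and 85.9% of those of replicate 2.

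Each sequence was put in 1 class, in this order: nuclear ribosomal RNA on the strand of the gene, taking 5900 bp from the start of each 18S gene as a unit because the annotation does not mark the 25S gene as ribosomal RNA, then transfer RNA, small nuclear or nucleolar RNA, chloroplast, mitochondrion, MIR gene, TAS locus, other nuclear sequence and no match. Small RNA reads are those in the MIR, TAS and other nuclear classes, 43.9% of the reads of replicate 1 and 49.3% of those of replicate 2. RPM values computed here are per 1000000 of these reads. Reads with several matches were divided equally among them. Counts of different sequences also carry the preferences of adapter ligation, so RPM values of different miRNAs compare reads and not molecules.

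The miRNA list had 103 mature sequences grouped by known role, with 4 trans-acting siRNAs and 1 siRNA of the 5S ribosomal DNA, each counted only when the sequence was identical over its full length. Of the 103, members of a family with the same sequence were counted once. Registers at TAS loci were counted in transcript coordinates for 21 nt reads, with antisense reads shifted by 2 nt, and the predicted cut was placed between bases 10 and 11 at the site with the fewest mismatches to the trigger miRNA. For TAS3a, where a pair of sites tied, the 5′ site was used and both are given. It was taken only because it comes first in the transcript, and which site is cut was not examined. Feature shares took the middle base of each 24 nt match. Windows of 1000 bp and bins of 1 Mb tiled the nuclear chromosomes.

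With 1 group of 2 libraries no condition could be compared, and permuting signs over 2 libraries cannot give a p below 0.5, so no such test was made. Means and SDs (n = 2) are given, and a difference between classes is said to exceed the spread when both libraries had the same order and the means differed by more than 2 times the larger SD. For a share in a single library the Wilson interval at a confidence level of 95% covers counting error only, and it was narrow at these depths, from 22.0% to 22.1% for the 24 nt share of replicate 1. The limit for a count of 0 is 3 reads, 0.487 RPM in replicate 1 and 0.263 RPM in replicate 2, and covers counting error only. The libraries were compared per miRNA with an exact two-sided binomial test given their numbers of small RNA reads, for miRNAs with at least 10 reads in both together. This test covers counting error only and not amplification or library preparation, and ratios between the libraries were taken after adding 0.5 reads to each count, which understates the ratio of miRNAs with few reads. edgeR 4.0.16 in R 4.3.3 gave the biological coefficient of variation (estimateDisp, intercept only) and TMM factors from 97044 sequences with at least 10 reads. On simulated counts of the 76 miRNAs compared, the binomial test recovered 83.5% of miRNAs changed by 2-fold and called 0.909% of unchanged ones. Those counts held counting error only. The listed miRNAs had a biological coefficient of variation of 0.374, so these rates do not carry over to the libraries. For the search for phased genes, 0% of 200 simulated loci with no phasing passed, and 100% of 200 simulated loci with 50% of positions phased passed. These sets of loci differed in the percent of positions phased. A simulated locus passed with the same best register in both libraries and at least 30% of reads in it. The limits on single sequences and antisense reads were not applied there, so these are not the rates of the full search. Loci where 1 sequence gives a large share of the reads, or where antisense reads are few, were not simulated as a set. The rates may therefore not carry over to such loci.

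Named in the text are the 25 families with the highest mean RPM, the miRNAs with 0 reads in both libraries, every TAS locus and listed siRNA, the 3 miRNAs with at least 100 reads in both libraries together and the largest ratio between them, and the 5 windows with the most 24 nt reads and the 5 with the most 21 nt reads outside MIR and TAS genes. Other names given as examples of a list or in the closing observations were chosen after their values were seen. These lists, tests and most alternatives were fixed before the data were examined. The alternatives were a length range of 20 to 25 nt, distinct sequences in place of reads, sequences with at least 2 reads, all reads or structural RNA and organelle reads kept, miRNA ends that differ by up to 2 nt, TMM scaling, uniquely matching reads, 20 to 22 nt reads at TAS loci, 23 nt reads joined to the 24 nt class, at least 100 reads per miRNA, and each library alone. Alternatives chosen after seeing the data left out reads of MIR165 and MIR166 genes, left out the most-read 21 nt sequence of each TAS locus, and counted tailed and shortened forms of miR158a. Transposable elements were not analysed here as a class of their own, since the annotation used has none. The pseudogene class follows the annotation, and whether it holds transposable elements was not examined. The targets of the small RNAs were not analysed here.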

Results

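Small RNA was sequenced from Arabidopsis thaliana seedlings of the Columbia (Col) ecotype, wild type, grown for 10 days in continuous light. The labels name the tissue as the whole bud of the seedling and carry the mark 22c, whose meaning they do not give. There was 1 group of 2 libraries, called replicate 1 and replicate 2, and each library was given as a list of distinct sequences of 18 to 30 nt with the number of reads of each. Replicate 1 held 14006983 reads of 1746654 distinct sequences and replicate 2 held 23141019 reads of 3076412 distinct sequences. The study set out to link the small RNAs of wild-type seedlings to the pathways that make them, so the libraries were described by size, first base, origin and locus. No condition was compared. Values are means ± SD over the 2 libraries, and RPM stands for reads per 1000000 small RNA reads, which are genome-matched reads outside structural RNA genes and organelle genomes.

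MicroRNA (MIR) genes, ribosomal RNA and other nuclear sequence were the 3 main sources of reads. MIR genes gave 26.1% ± 2.23 of all reads, nuclear ribosomal RNA gave 25.5% ± 4.11 and other nuclear sequence gave 19.8% ± 5.82 (SD, n = 2), and the order of these sources was not the same in both libraries. Chloroplast sequences took 11.9% ± 0.195 of the reads, far above mitochondrial sequences at 0.580% ± 0.200. Nuclear transfer RNA fragments took 1.54% ± 0.668 and fragments of small nuclear and small nucleolar RNA took 0.193% ± 0.0298. Loci of trans-acting siRNA (TAS loci) gave 0.749% ± 0.193. A further 13.7% ± 0.571 of the reads had no perfect match in the genome. By distinct sequences in place of reads, 1.58% came from nuclear ribosomal RNA, 3.64% from the chloroplast and 40.3% had no match. The difference between ribosomal and chloroplast shares was 13.6 percentage points, larger than the replicate spread. The small RNA reads that remained for the analyses of size, first base and position numbered 6155738 in replicate 1 and 11408133 in replicate 2.

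Reads of 21 nt, the size made by DICER-LIKE1 and DICER-LIKE4, were the most abundant class, and reads of 24 nt, the size made by DICER-LIKE3 in the RNA-directed DNA methylation pathway, came next. They took 54.3% ± 8.39 and 25.9% ± 5.44 of the small RNA reads, a difference of 28.4 percentage points that had the same sign in both libraries and lay beyond the replicate spread. Over all reads of the files, matched or not, the shares were 32.5% ± 1.48 and 20.04% ± 2.54. The 21 nt share was 60.3% in replicate 1 and 48.4% in replicate 2, and the 24 nt share was 22.1% and 29.8%. Reads of 23 nt took 7.19% ± 2.39, reads of 22 nt 6.01% ± 0.615 and reads of 20 nt 3.30% ± 0.148, and the 23 nt and 22 nt classes were not separated by more than the spread. Among distinct sequences the order was turned, with 49.1% ± 2.80 at 24 nt and 8.18% ± 0.403 at 21 nt. A distinct 21 nt sequence was read 52.1 times on average in replicate 1 and 40.1 times in replicate 2, and a distinct 24 nt sequence 2.95 and 4.44 times. The 21 nt means rest largely on the single sequence of mature miR166, which gave 39.7% and 28.4% of the small RNA reads. The order of 21 nt and 24 nt reads also turned when reads of the MIR165 and MIR166 genes were left out, a setting chosen after seeing the data, to 18.2% ± 1.80 and 49.1% ± 1.24.

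**Figure D1:**
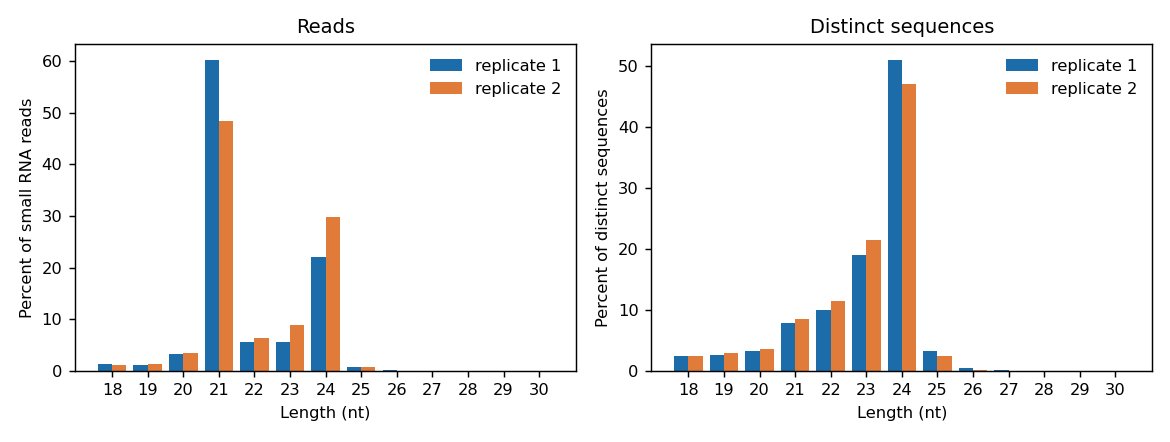
Share of each length from 18 to 30 nt among small RNA reads (left) and among distinct small RNA sequences (right), in percent, with 1 bar per library. Reads peaked at 21 nt with 60.3% and 48.4%, and distinct sequences peaked at 24 nt with 51.0% and 47.1%.

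The classes came from different loci. MIR genes gave 93.5% ± 2.06 of the 21 nt reads, TAS loci gave 1.58% ± 0.357 of them, and other nuclear sequence gave 4.90% ± 1.70. At 22 nt, MIR genes gave 38.7% ± 12.1 of the reads. At 24 nt, MIR genes gave 0.465% ± 0.0309 of the reads and TAS loci 0.734% ± 0.109.

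The first base, by which ARGONAUTE proteins sort small RNA, differed between the size classes. T (uracil in the RNA) opened 94.1% ± 2.25 of the 21 nt reads and A opened 59.5% ± 1.80 of the 24 nt reads (SD, n = 2), the bases favoured by ARGONAUTE1 and by ARGONAUTE4 and its relatives. T opened only 18.1% ± 0.530 of the 24 nt reads, and A opened 2.63% ± 0.795 of the 21 nt reads, and both differences between the classes were larger than the libraries differed from each other. The 22 nt reads had T at 58.0% ± 7.93 and A at 16.1% ± 2.25. In the 23 nt reads A led by less, with A at 33.6% ± 0.778 and T at 27.2% ± 1.23. Among distinct 21 nt sequences T opened 29.9% ± 1.22 and A 32.6% ± 1.54, so the T share of the 21 nt class lay in its abundant sequences. Among distinct 24 nt sequences A still led with 49.2% ± 2.78.

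The mature miRNAs of a list of 103 sequences made up 48.8% ± 9.22 of the small RNA reads, and miR166 and miR165 alone took 85.9% ± 2.97 of that. Both target the class III homeodomain leucine zipper genes of leaf and vascular patterning. Mature miR166, TCGGACCAGGCTTCATTCCCC, matched 7 MIR166 genes, among them MIR166a (AT2G46685, chromosome 2, 19176241 to 19176261, plus strand), and stood at 340413 RPM ± 80196. Mature miR165 of MIR165a (AT1G01183, chromosome 1, 78932 to 78952, minus strand) and MIR165b stood at 79626 RPM ± 13455. All other listed miRNAs together came to 6.75% ± 0.144 of the small RNA reads, 6.65% in replicate 1 and 6.85% in replicate 2. This nearness depends on the base. Of the reads left without the MIR165 and MIR166 genes, a base chosen after seeing the data, they took 14.5% in replicate 1 and 11.5% in replicate 2. Of the 103 miRNAs, 84 were read in both libraries, 5 in 1 library only and 14 in neither.

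After these, the development families were led by miR396, which targets growth-regulating factors, at 17182 RPM ± 610.0, and miR159, which targets MYB genes, at 6844 RPM ± 160.7. They were followed by miR319, whose targets include TCP genes, at 925 RPM ± 119, miR167 at 252 RPM ± 43.5, miR394 at 92.9 RPM ± 38.7 and miR171 at 43.1 RPM ± 22.8. The family miR164, which targets NAC genes, was almost not read, with 3 and 4 reads of miR164a-b. The phase change families were uneven. The juvenile families miR157 and miR156, which target SPL genes, stood at 2739 RPM ± 340.2 and 2627 RPM ± 571, while their adult counterpart miR172 had 6 reads in replicate 1 and 170 in replicate 2. The 3 miRNAs that target the small RNA machinery were all abundant, with miR403 (target AGO2) at 2216 RPM ± 44.4, miR162 (target DCL1) at 1442 RPM ± 350.4 and miR168 (target AGO1) at 1343 RPM ± 469.

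Nutrient-responsive miRNAs were split. The copper families, which are induced when copper is short, were high at 16988 RPM ± 64.2 together. Of these, miR398 gave 13598 RPM ± 337, miR408 gave 2942 RPM ± 220 and miR397 gave 446 RPM ± 53.9, and miR857 had 7 reads in each library. The phosphate list came to 224 RPM ± 59.1, of which miR399 gave 204 RPM ± 56.04 and miR827 gave 20.1 RPM ± 3.03, and neither miR2111a-b nor miR778 was read. The sulfate family miR395 stood at 4.50 RPM ± 2.69. The pollen marker miR845a had 10 and 67 reads, 3.75 RPM ± 3.004.

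Families known mainly from Arabidopsis and its relatives were led by miR158 at 11557 RPM ± 80.5. With forms that carry untemplated tails or lack end bases, miR158a came to 32744 RPM ± 3507, above the exact matches of miR396. Below it stood miR163 at 200.4 RPM ± 37.6, miR822 at 102 RPM ± 22.6, miR775 at 83.7 RPM ± 39.7, miR846 at 59.6 RPM ± 0.230 and miR847 at 50.8 RPM ± 14.1. Among miRNAs that start secondary siRNA, miR161 stood at 1713 RPM ± 21.9, miR390 at 371 RPM ± 109 and miR173 at 31.1 RPM ± 12.7. The miRNAs with 0 reads in both libraries were miR172e, miR399e, miR2111a-b, miR778, miR828, miR845b, miR771, miR774a, miR776, miR780.1, miR834, miR856, miR864-5p and miR868. A count of 0 allows up to 0.487 RPM in replicate 1 and 0.263 RPM in replicate 2. Of the 24 pairs of neighbouring ranks among the 25 leading families, 9 differed by more than the spread between replicates, for exact matches in RPM. Among them was every step from miR166 down to miR408. With TMM scaling the SDs grew, and most of these steps lay within the spread. There miR166 stood at 378791 ± 175331 and miR165 at 87913 ± 35273, and miR398 at 14759 ± 3902 and miR158 at 12517 ± 3094. With ends that could differ by up to 2 nt, miR158 at 14158 RPM ± 143 lay above miR398 at 13771 RPM ± 307, and 6 families rose more than 1.5-fold. These were miR775 at 258.8 RPM, miR161 at 3173 RPM, miR168 at 2372 RPM, miR319 at 1612 RPM, miR408 at 5032 RPM and miR394 at 156.1 RPM.

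**Figure D2:**
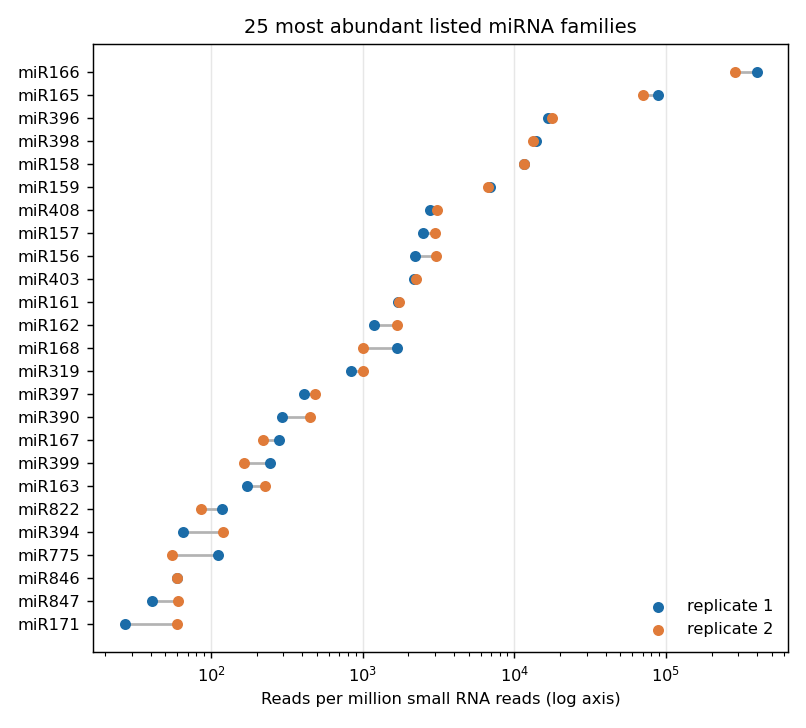
RPM (log axis) of the 25 listed miRNA families with the highest mean, with 1 point per library and a line between the 2 points. The families ran from miR166 at 340413 RPM to miR171 at 43.1 RPM, and the points of miR158 and miR846 nearly coincided.

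TAS loci make long RNAs that are cleaved by a miRNA and then diced into 21 nt siRNA in steps of 21 nt. The 8 loci together gave 8410 RPM ± 606 of 21 nt reads, and 13490 RPM ± 2702 with 20 nt and 22 nt reads added. TAS1c (AT2G39675, chromosome 2, 16537288 to 16538277, minus strand) was the highest at 3945 RPM ± 131, above TAS2 (AT2G39681, chromosome 2) at 1727 RPM ± 313 by more than the spread between replicates. TAS3a (AT3G17185, chromosome 3), the source of siRNA against auxin response factors, stood at 1407 RPM ± 629, and TAS2 and TAS3a were not separated. TAS1b (AT1G50055) gave 473 RPM ± 20.7, TAS1a (AT2G27400) 465 RPM ± 27.0, TAS3b (AT5G49615) 205 RPM ± 97.8, TAS4 (AT3G25795) 181 RPM ± 11.2 and TAS3c (AT5G57735) 5.77 RPM ± 1.26. At TAS3b, 92.9% and 95.8% of these reads came from 1 sequence that also matches TAS3a and was divided equally between them. Without it 59 and 130 reads were left, so the TAS3b level rests on reads that may come from TAS3a.

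At 5 of the 8 loci, the most filled of the 21 possible registers in both libraries was the register that starts where the trigger miRNA is predicted to cut, between its bases 10 and 11. This register held 71.1% ± 1.92 of the 21 nt reads at TAS1c, 48.4% ± 4.95 at TAS1b and 45.0% ± 0.392 at TAS1a, for cuts by miR173. It held 71.7% ± 4.06 at TAS4, whose trigger miR828 had 0 reads in both libraries, and 65.2% ± 2.67 at TAS3c for miR390. TAS3c had 30 and 76 reads of 21 nt, and the single sequence TTGGTTTGTTGTTTCTATTCC gave 18 and 50 of them. With the most-read sequence of each locus left out, a setting chosen after seeing the data, 4 loci had their best register there in both libraries, TAS1a, TAS1c, TAS2 and TAS4. At TAS1c the median register held 0.326% in replicate 1 and 0.335% in replicate 2. However, a single sequence, TTCTAAGTTCAACATATCGAC, gave 13673 of the 23715 reads of 21 nt at the locus in replicate 1. By distinct sequences the best register of TAS1c held 9.27% ± 0.487. At TAS2 the predicted register ranked second in replicate 1 with 26.6% and first in replicate 2 with 41.6%. In replicate 1 it was passed by a register that held 55.3%, where a single antisense sequence, TTTGCATATACTCGAATACCT, gave 5541 of the 11994 reads of 21 nt. TAS3a has a pair of miR390 sites with 5 mismatches each. The register of the 5′ site held 23.96% and 30.99%. That of the 3′ site, which is register 13 counted from the 5′ cut, held 7.11% and 5.46%. The 5′ register had rank 2 in replicate 1, behind register 11 from the 5′ cut with 25.5%. It had rank 1 in replicate 2, where register 11 held 23.7%. Registers 10 and 12 held 15.8% and 15.8% in replicate 1 and 19.1% and 10.6% in replicate 2. Registers 10 to 12 thus lay close to register 13 of the 3′ site, and why they were filled was not tested. Without the most-read sequence of the locus the 5′ register held 10.1% and 8.35%, rank 4 in both libraries. Neither site was thus shown to set the register at TAS3a. At TAS3b neither miR390 site set the main register, and 94.5% ± 1.999 of the 21 nt reads lay in a register 1 nt from that of the 5′ site. There the sequence TTTTCTTGACCTTGTAAGACC, shared with TAS3a, gave most reads.

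**Figure D3:**
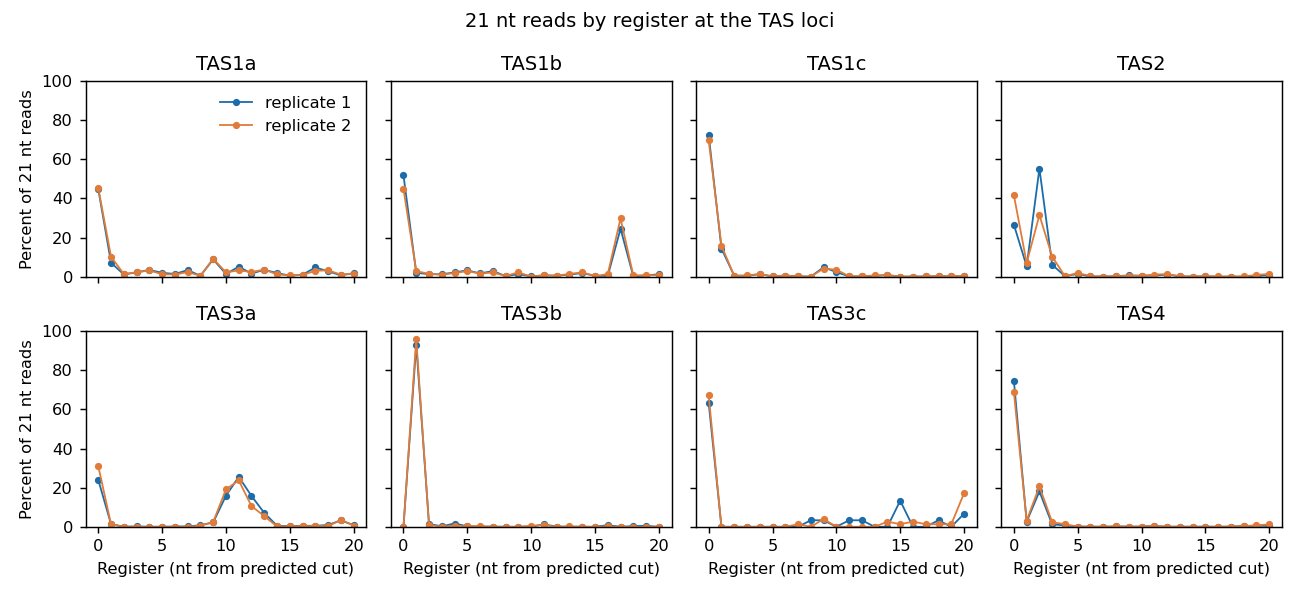
Percent of 21 nt reads in each of the 21 registers at the 8 TAS loci, counted in nt from the predicted cut of the trigger miRNA, with 1 line per library. Register 0 was the highest in both libraries at TAS1a, TAS1b, TAS1c, TAS3c and TAS4, with 71.1% ± 1.92 of the reads at TAS1c.

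Single trans-acting siRNAs of the list were read at moderate levels. The TAS3-derived siRNA against auxin response factors known as D7, TTCTTGACCTTGTAAGACCCC, stood at 83.1 RPM ± 14.4 and its neighbour D8 at 11.4 RPM ± 8.07. The TAS1 siRNA siR255 stood at 42.2 RPM ± 0.291. The listed sequence of TAS2 siR1511 had 0 reads, while its reverse complement, TCCAAGCGAATGATGATACTT, which is the sense strand of TAS2, stood at 379 RPM ± 63.1. The 24 nt siRNA siR1003 of the 5S ribosomal DNA stood at 308 RPM ± 127. TAS1c had the largest share of 22 nt reads, 37.2% ± 11.8 of all its reads, but the difference from TAS1a at 21.4% ± 0.623 lay within the replicate spread. Most of them were the antisense sequence TCCAATGTCTTTTCTAGTTCGT (chromosome 2, 16537796 to 16537817), with 1892 RPM in replicate 1 and 4595 RPM in replicate 2.

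The 24 nt reads lay mainly between genes and in annotated pseudogenes, a class not checked for transposable elements. Intergenic sequence held 63.8% ± 0.525 of the 24 nt reads against 35.9% of the nuclear genome, and pseudogenes held 20.9% ± 0.480 against 8.78%. Exons of protein-coding genes held 8.33% ± 0.212 against 38.9% and introns 3.20% ± 0.0693 against 15.1%. All 4 shares lay farther from the genome share than 2 times the larger SD. Along the chromosomes, the 24 nt reads rose in regions dense in pseudogenes. On no chromosome was the highest 24 nt bin of 1 Mb the bin with the most pseudogene cover. The highest bin had 43.2% cover on chromosome 3 and 21.6% on chromosome 4. Bins with 47.4% and 48.8% lay elsewhere on these chromosomes. The highest bin of 1 Mb on chromosome 3 (14000001 to 15000000) held 7655 RPM as the mean of 5872 and 9439 RPM, 6.195 times the median bin of that chromosome, and the highest bin on chromosome 2 (2000001 to 3000000) held 2.94 times its median. Over 121 bins, the rank correlation between 24 nt reads and pseudogene cover was 0.875 in replicate 1 and 0.859 in replicate 2, and for 21 nt reads of other nuclear sequence it was 0.797 and 0.828. This is a correlation across bins within a library, and neighbouring bins are not independent replicates.

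**Figure D4:**
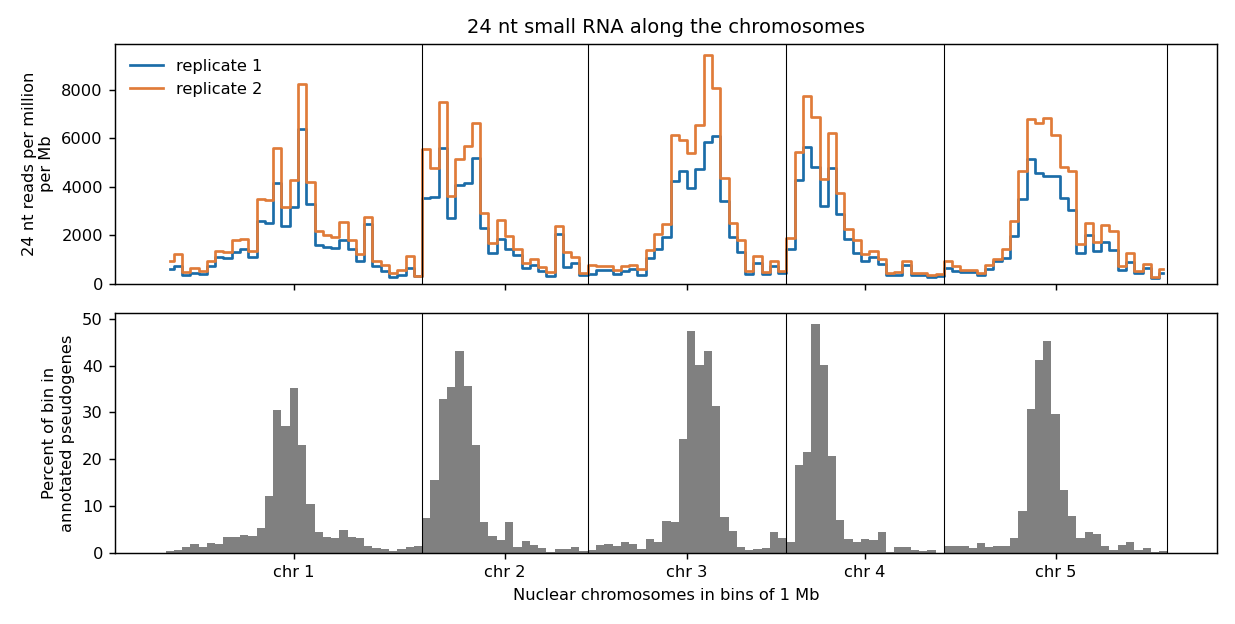
Reads of 24 nt in RPM per Mb (top, 1 line per library) and percent of each bin in annotated pseudogenes (bottom) over bins of 1 Mb along the 5 nuclear chromosomes, separated by vertical lines. On chromosome 3 replicate 1 was highest in the bin from 15000001 to 16000000, at 6082 RPM, and replicate 2 in the bin before it, at 9439 RPM.

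The 24 nt reads were spread over many places, with 3079 of 119149 windows of 1000 bp giving 50% of them. The highest window, on chromosome 2 from 16537001 to 16538000, covered part of TAS1c and held 1569 RPM ± 119, of which 62.9% came from a single sequence. The next was on chromosome 1 from 24721001 to 24722000, at 991 RPM ± 77.2, over the noncoding genes AT1G09805 and AT1G08833. A window on chromosome 4 from 2073001 to 2074000, between genes, held 674 RPM ± 320.2. A window on chromosome 1 from 11662001 to 11663000, over the protein-coding gene AT1G32337, held 599 RPM ± 208, of which 87.0% came from the single sequence ATTCCTCATCTCCGCTCGGATCTG. The fifth was on chromosome 3 from 14195001 to 14196000, at 586 RPM ± 356, over the genes AT3G41762 and AT3G41761. Uniquely matching reads gave only 35.4 of its 334 RPM in replicate 1 and 206 of 838 RPM in replicate 2. The rest was placed by equal division among matches.

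Outside MIR and TAS genes, 21 nt reads came to 25924 RPM, and 1327 windows gave 50% of them while the 5 highest gave 9.57%. The highest, on chromosome 5 from 22322001 to 22323000 over the protein-coding gene AT5G55010, held 795 RPM ± 95.1. The window on chromosome 3 from 16160001 to 16161000, over AT3G44580, held 387 RPM ± 56.3. The other 3 of the 5 highest windows lay over ribosomal DNA, on chromosome 3 from 14199001 to 14200000 at 522 RPM ± 359, on chromosome 2 from 5001 to 6000 at 484 RPM ± 340.4, and on chromosome 3 from 14203001 to 14204000 at 293 RPM ± 158.2. Their reads came almost wholly from the strand opposite to the ribosomal RNA, since reads of the same strand were counted as ribosomal RNA fragments.

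The replicates ranked the miRNAs alike. Across 76 miRNAs with at least 10 reads, Spearman's rho was 0.960, and 61 miRNAs lay within 2-fold, though miRNAs are not independent replicates. An exact two-sided binomial test of the reads of each miRNA, which compares these libraries and not conditions, found 51 of the 76 different at an adjusted p under 0.05 (Benjamini-Hochberg, adjusted over the list alone). The test takes reads as independent and covers neither copies made by amplification nor library preparation, and at these depths it called even small differences, such as that of miR158a (log2 ratio -0.015, adjusted p = 0.0388). Of the 51, 33 were higher in replicate 2 and 18 were lower. With edgeR's TMM scaling, 17 of 50 were higher in replicate 2, and with all reads as the denominator 40 of 52 were. With 0.5 reads added to each count, the largest ratios were those of miR172a-b, with 6 against 164 reads (log2 ratio 3.77, adjusted p = 1.02e-22), miR472 with 34 against 237 reads (log2 ratio 1.89, adjusted p = 3.02e-16) and miR170 with 31 against 205 reads (log2 ratio 1.82, adjusted p = 1.03e-13), all higher in replicate 2. The biological coefficient of variation that edgeR estimated for the listed miRNAs was 0.374. Of the distinct small RNA sequences, 16.7% were in both libraries, and these held 89.7% of the reads of replicate 1 and 82.0% of those of replicate 2.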

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

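Each of these results is a signal in reads that the comparisons of the report left aside, and each lay above the limit that a count of 0 allows. With 2 libraries no sample can be tested as standing apart from its group, and with 1 group there is no difference between groups to test. All tests in this part were chosen after the results were seen.

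Mature miR158a (TCCCAAATGTAGACAAAGCA, MIR158a, AT3G10745, chromosome 3, 3366349 to 3366368, minus strand) carried 3′ tails that do not match the genome. Of its reads, 44.9% ± 2.73 (SD, n = 2) ended in an untemplated tail of T only and 41.7% ± 4.06 were templated, so the exact match counted in the report misses much of this miRNA. A sequencing or trimming error common to all miRNAs would give a like share everywhere, but the share was at least 32.3 times the median over the other 25 of the 26 miRNA groups measured, in both libraries. Left-over bases of the 3′ adapter, which begins with TGG, would give TG among tails of 2 nt. There TT was at least 656 times as frequent as TG. This test does not cover tails of a single T, which 1 left-over base would also give. The most-read tailed form had a single T, with 28529 and 40567 reads. Enzymatic addition of uridine may be the source, as a hypothesis, and no biological explanation was tested since the design has 1 group.

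A 22 nt RNA of the chloroplast inverted repeat, AGTTACTAATTCATGATCTGGC, was the most abundant chloroplast sequence. It lies at positions 97155 to 97176 (minus strand) and 141473 to 141494 (plus strand) of the chloroplast genome, each overlapping an annotated ndhB gene, and stood at 24539 ± 67.1 per 1000000 reads of the file, 20.9% and 20.5% of the chloroplast reads. Random breakdown of a longer transcript would give scattered ends, but at least 99.3% of the reads on its strand within 30 nt shared its first base in each library. A nuclear copy would need a match there, and the sequence had 0 perfect nuclear matches. A stable end left where a bound protein stops a nuclease may account for it, as a hypothesis, and no biological explanation was tested.

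Of the 30 nt reads, 65.0% held the first bases of the 3′ adapter inside the sequence, 61.4% in replicate 1 and 68.6% in replicate 2.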

How the results depend on the processing

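No paired analysis was possible because there was 1 group, and classes of reads were compared within each library without a test. With each library taken alone, values lay within 1 SD of the mean, as any 2 values do, and ranged from 48.4% to 60.3% for the 21 nt share, 22.1% to 29.8% for the 24 nt share, 5.58% to 6.45% for the 22 nt share, 92.6% to 95.7% for T in the 21 nt class, 58.2% to 60.8% for A in the 24 nt class, 42.2% to 55.3% for the listed miRNAs, 7981 to 8838 RPM for the TAS loci, 69.8% to 72.5% for the best TAS1c register, 63.4% to 64.1% for intergenic, 20.6% to 21.3% for pseudogene and 8.18% to 8.48% for exon shares, and 22.6% to 28.4%, 11.7% to 12.0% and 13.3% to 14.1% for ribosomal, chloroplast and unmatched reads. Distinct sequences in place of reads, which weigh each sequence once, gave 8.18%, 10.7% and 49.1% for the 21, 22 and 24 nt shares, 29.9% and 49.2% for the first bases T and A, 137 RPM and 9.27% for the TAS loci and the TAS1c register, 55.1%, 31.02% and 8.91% for intergenic, pseudogene and exon shares, and 1.58%, 3.64% and 40.3% for ribosomal, chloroplast and unmatched sequences. With all reads as the base the 21, 22 and 24 nt shares were 32.5%, 11.3% and 20.04%, and the listed miRNAs took 22.6%, since the base grows by structural, organelle and unmatched reads. With structural RNA and organelle matches kept the shares were 34.9%, 11.1% and 20.2%, T opened 81.1% of the 21 nt reads and A 46.9% of the 24 nt reads. Without MIR165 and MIR166 reads, chosen after seeing the data, the shares were 18.2%, 7.82% and 49.1%, T opened 70.6% of the 21 nt reads and the other listed miRNAs took 13.0%. Sequences with at least 2 reads gave A at 62.2% in the 24 nt class. With 20 to 22 nt reads the TAS loci gave 13490 RPM and the TAS1c register 52.0%, and without the most-read sequence of each locus, chosen after seeing the data, they gave 4942 RPM and 39.1%. Loci with the best register at the predicted cut numbered 5, and 4 in these 2 settings and by distinct sequences, 5 with unique matches, 5 in replicate 1 and 7 in replicate 2. The 7 in replicate 2 include TAS3a, scored at its 5′ site. Uniquely matching reads gave intergenic, pseudogene and exon shares of 64.4%, 19.2% and 9.05%, and 23 nt reads added to the 24 nt class gave an exon share of 8.58%. Lengths of 20 to 25 nt gave 20.9%, 10.5% and 12.4% for ribosomal, chloroplast and unmatched reads. For the shifts with sequences read at least 2 times, unique matches, 23 nt reads and lengths of 20 to 25 nt, the cause was not tested. The number of miRNAs the binomial test called different between the libraries was 51, and 48, 50 and 52 with at least 100 reads, TMM scaling and all reads as the base. Of 98 values of the 25 families under other settings, each library alone not counted, 69 moved by 1 SD or more. Of these, 24 came with all reads as the base and 23 without MIR165 and MIR166 reads, changes of base that scale the families together. Ends that differ by up to 2 nt moved 15 and TMM scaling moved 7. With such ends, 22 of the leading families stayed among the first 25. Depth limits miRNAs of a few reads, such as miR164 and miR172, whose levels rest on under 10 reads in replicate 1.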

Other observations

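Several abundant products of MIR genes were outside the miRNA list. Among annotated mature sequences the highest was the 5′ arm of MIR166a and MIR166b, GGACTGTTGTCTGGCTCGAGG (chromosome 2, 19176128 to 19176148 in MIR166a), at 885 RPM in replicate 1 and 3150 RPM in replicate 2, while the 3′ arm, mature miR166, went from 397120 RPM to 283705 RPM between the same libraries. The 3′ arms of MIR157c and of MIR157a and MIR157b stood at 546 RPM ± 176 and 368 RPM ± 37.6, and the 3′ arm of MIR824 at 318 RPM ± 58.6, above the listed miR824 at 37.3 RPM ± 12.7. The 3′ arms of MIR169f and MIR393b stood at 204 RPM ± 77.5 and 186 RPM ± 9.29. Mature miR166 also had forms that start 1 base earlier and match only MIR166a, of 21 nt (TTCGGACCAGGCTTCATTCCC, 23089 RPM and 21797 RPM) and of 22 nt (TTCGGACCAGGCTTCATTCCCC, 19206 RPM and 12812 RPM).

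Tails other than those of miR158a were uneven as well. Tails of T only were on 44.6% ± 3.15 of the reads of miR319, 30.8% ± 4.10 of miR775 and 26.1% ± 9.34 of miR156a-f, against 0.0799% ± 0.0225 of miR166. On miR157a-c, 14.1% ± 3.45 of the reads had a tail of C only, and on miR161.1 6.46% ± 0.5003 had a tail of G only. Among protein-coding genes, noncoding genes and pseudogenes outside MIR and TAS loci, 51 had at least 100 reads of 21 nt in each library, and 2 of them met the limits set for phased siRNA in both libraries, at least 30% of reads in 1 register, no sequence above 20% and 10% to 90% of reads antisense. They were AT1G63150 (chromosome 1, 23419294 to 23421714), with 42.4% and 30.7% of its 21 nt reads in the same register, and AT1G62910 (chromosome 1, 23298948 to 23301141), with 39.6% and 33.2%. AT1G63150 lay at the edge of the limits, since its most-read sequence gave 19.98% of the reads in 1 library. Of the same region, AT1G63070 had 40.8% and 43.5% in the same register and AT1G63080 had 35.8% and 29.6%, and neither met the limits, with up to 32.4% and 22.6% of the reads in 1 sequence.

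The tests of the 24 nt share that follow were chosen after it was seen, and the test of the TAS registers was set before. Replicate 2 had the larger share of 24 nt reads, by 7.69 percentage points. If miR165 and miR166 reads had only diluted the other classes of replicate 1, the difference would shrink without them, and it shrank to 1.75 percentage points, 48.24% against 49.996%. A different size selection of the libraries could raise the ratio of 24 nt to 21 nt reads in organelle RNA as well. That ratio in replicate 2 was 1.03 times that in replicate 1, which covers these lengths only. Of all reads, those of 25 nt took 4.33% in replicate 1 and 2.47% in replicate 2, and those of 26 nt took 1.84% and 0.784%. The libraries thus differed at longer lengths, and a different size selection was not excluded. Dilution alone would also leave every other class at the same share of the reads that remain, but the share of the other listed miRNAs fell from 14.5% to 11.5% and that of 23 nt reads rose from 12.01% to 14.9%. With 1 library on each side these changes have no spread, so dilution and size selection were both left open as sources of the larger 24 nt share. For the TAS loci the hypothesis was that the cut of the trigger miRNA sets the register, and 5 of the 8 loci had their best register there in both libraries, the smallest number set as a positive outcome. It fell to 4 with 20 nt and 22 nt reads added, with distinct sequences in place of reads, and without the most-read sequence of each locus. The outcome for the 8 loci as a set thus depended on the setting and is left open here. With and without the most-read sequence, TAS1a, TAS1c and TAS4 had their best register there in both libraries. Without it TAS2 joined them and TAS1b and TAS3c dropped out, while TAS3a and TAS3b met the rule in neither setting.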
